A study of Mus musculus with 3 samples.

How the data were processed

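Total RNA was extracted with TRIzol from brains of adult wild-type C57BL/6 mice, checked on an Agilent Bioanalyzer and sequenced on the Illumina HiSeq platform, per the labels and the series' design text. There were 3 libraries, 1 each for the sham, vehicle and AGNHW groups, and they were grouped by their titles. The brain region, the time after occlusion, the number of mice behind each library and the strand setting of the counting are not given in the sources used here.

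The authors deposited whole-number read counts per gene symbol for each library, with no normalisation. Per the submitters' processing notes, Bowtie2 2.2.3, TopHat2 2.0.12 and HTSeq 0.6.0 were used with the mouse build mm9; the order of these steps and their settings are not given in the sources used here. The same 17992 symbols were listed for each library, and the lowest sum of a gene over the 3 libraries was 21, so genes of lower counts had been left out of the deposited counts before this work. Some symbols are later than the mm9 annotations, so no coordinates are printed. With the strand setting unknown, reads of overlapping and antisense genes cannot be told apart. Genes with near-identical copies are given as uncertain, because reads can be split between copies in ways that depend on settings that are not known.

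The libraries held 18286151 counts (sham), 15718594 counts (vehicle) and 18184691 counts (AGNHW). Counts were scaled with the trimmed mean of M-values (TMM) of edgeR 4.0.16 in R 4.3.3, with factors of 1.03, 0.968 and 1.0 in that order, and are given as CPM, that is scaled to a common library total. Gene lists, intervals and figures were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The floor used for a gene at 0 was 3 counts per library, which is 0.159 CPM in sham, 0.197 CPM in vehicle and 0.164 CPM in AGNHW. A fold against a library at 0 was computed against this floor and is written as a lower bound.

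With 1 library per group, no spread between animals could be estimated, so no test of the conditions was made and no p-value is given. A comparison of 2 libraries is of those libraries, not of the conditions. A size rule was fixed before the data were examined, as were the gene lists, the rule for named genes and the alternatives, except where a choice is said to have come later. A gene passed the size rule when its ratio of TMM-scaled CPM was at least 1.5 either way, its mean CPM over the 3 libraries was at least 1 and the 95% exact conditional binomial interval of the ratio excluded 1. This left 15558 genes to compare. Intervals and floors cover counting error only. The intervals may be too narrow even for that, since reads without molecular identifiers are not independent molecules.

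Log2 ratios were computed with a prior count of 5 scaled to library size. The median log2 ratio of each of 42 gene lists was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins, and is given as a percentile that describes these libraries. The lists held 1078 entries (1036 distinct symbols), of which 986 were among the counted genes, 1 of them by an older symbol. If the members of a list varied independently, 1.05 lists would be expected beyond each end of the central 95% of random lists. Genes of a cell type or pathway can vary together and some lists share members, so a larger number does not by itself show an excess over chance. The lists covered neural progenitors, angiogenic factors, neurotrophic factors, Wnt signalling, cell division, cell types of the brain and its vessels, brain regions, the pituitary, responses to injury, and signs of other tissues or of RNA quality.

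Named genes were, in each comparison, the 10 highest and 10 lowest by log2 ratio among genes that passed the size rule, had at least 50 counts in the higher library and did not have a predicted or clone name. To these were added the 3 members of each list with the largest absolute log2 ratio. Dcx, Nes, Sox2, Mki67, Vegfa, Kdr, Pecam1, Cldn5, Bdnf, Gfap and Aif1 were always included, because the series asks about neurogenesis and angiogenesis. Genes named outside this rule were chosen after their values were seen and are said to be so.

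The size rule was tested on simulated counts drawn from the real means and totals of the 15558 genes. With counting error only, 119 unchanged genes passed it between vehicle and sham, 130 between AGNHW and vehicle and 98 between AGNHW and sham. Genes made 2-fold higher were recovered in 100%, 96% and 96% of cases in the same order. In a separate simulation at a fixed pair of mean counts, not those of the real genes, the counting intervals held the true ratio in 96.0% of cases. With an assumed coefficient of variation of 0.2 between samples, a value that was not measured here, 2567, 2530 and 2633 unchanged genes passed, and genes made 2-fold higher were recovered in 64%, 82% and 86% of cases.

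The alternatives were plain CPM, the size factors of DESeq2 1.42.0, upper-quartile factors, no filter or a mean CPM of at least 10, a ratio of at least 2 or 3, libraries thinned to the smallest total, a prior count of 0.5 and lists without shared members. After seeing the data, a correction for transcript length and GC content was added. It subtracted from each log2 ratio the median of genes in the same of 10 by 10 bins of length and GC content, taken from the longest GENCODE M21 transcript of each symbol, and 15234 of the 15558 genes had a length. The result of this correction is called the corrected value.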

Results

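The data were read counts for 17992 gene symbols in 3 mouse brain libraries, with no replicate of any group. The sham library held 18286151 counts. The vehicle library, with 15718594 counts, came from the model of middle cerebral artery occlusion, in which a main artery of the forebrain is blocked. The AGNHW library, with 18184691 counts, came from mice given 3 mg per g per day of AGNHW (Angong Niuhuang Wan, a traditional Chinese medicine preparation). The labels state the occlusion for the vehicle group and do not repeat it for the AGNHW group. Most ratios below are given with their 95% counting interval, no difference has a replicate check, and "higher" or "lower" describes these libraries.

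The comparison of vehicle with sham asks how the brain with an occluded artery differed from the operated control. The vehicle library had more transcripts of pituitary hormones and of the lipocalin Lcn2, and fewer of interferon-stimulated, activity-induced and microglial genes. Growth hormone (Gh) had 39065 counts in vehicle and 0 in sham, at least 16111-fold higher. Lcn2, an iron-sequestering protein made by reactive astrocytes and neutrophils, was 39.7-fold higher (20.6 to 87.8). Among 27 measured interferon-stimulated genes, 24 were lower in vehicle and 0 higher, with a median log2 ratio of -1.56. Dcx, the doublecortin gene of newborn neurons, was 2.08-fold lower (1.76 to 2.47), but its corrected value lay inside the 1.5-fold limit.

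In all, 1348 genes passed the size rule as higher in vehicle and 2207 as lower, so 37.9% of them were higher; with plain CPM the numbers were 890 and 2836, or 23.9% higher. Of 42 gene lists, 10 had medians above and 8 below the central 95% of random lists. The log2 ratio followed transcript length and GC content, which together explained 47.0% of its variance over 9941 genes of at least 10 CPM. Of 10 equal bins of transcript length, the shortest had a median of 0.47 and the longest -0.44. After correction for this trend, 737 genes were higher and 1041 lower, of which 440 and 782 had also passed in the same direction without it.

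**Figure D1:**
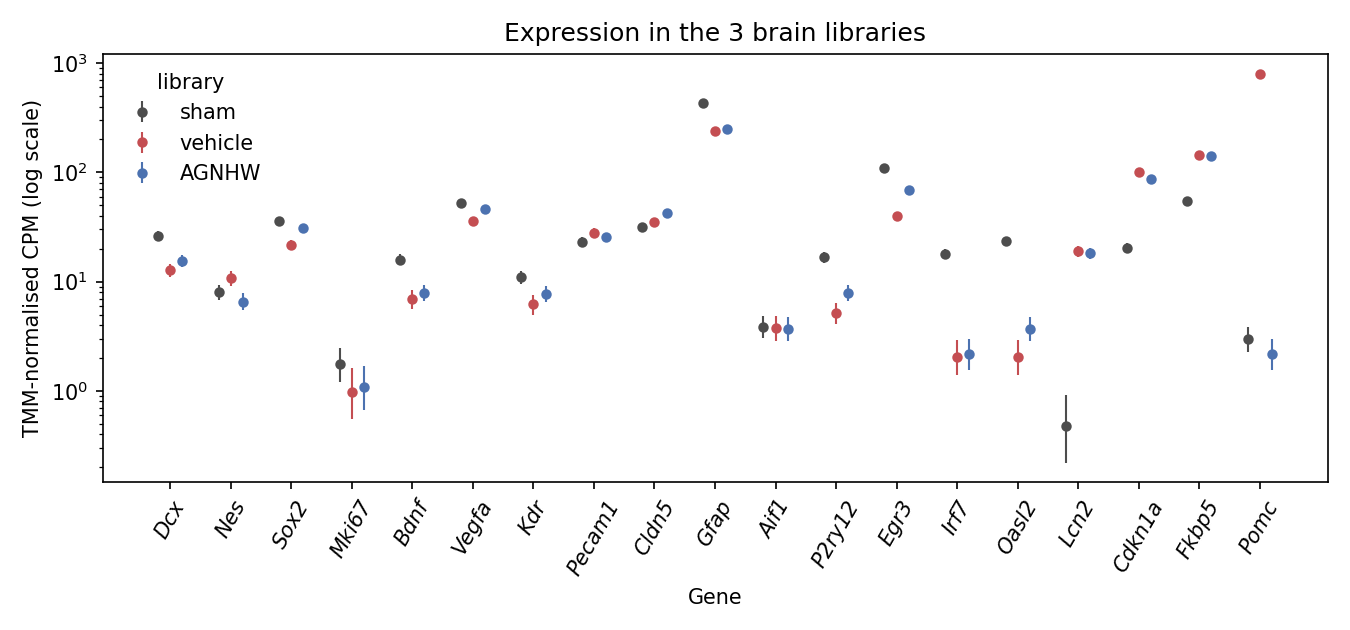
Expression of 19 genes in the sham, vehicle and AGNHW libraries, as TMM-scaled CPM on a log axis, with 95% Poisson intervals that cover counting error only. Lcn2 lay at 0.478 CPM in sham against 19.0 in vehicle and 18.2 in AGNHW, Irf7 at 17.9 against 2.04 and 2.19, and Pomc was high in the vehicle library alone of these 3.

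The interferon-stimulated genes, which answer antiviral signalling, formed the list with the lowest median in vehicle against sham, below every one of the 10000 random lists. Oasl2 was 11.5-fold lower in vehicle (8.0 to 17.2), Ifit1 13.3-fold lower (7.07 to 28.3) and Ifi44 25.9-fold lower (6.87 to 218), the last with 64 counts in sham and 2 in vehicle. Irf7, a transcription factor of the interferon response, was 8.79-fold lower (6.07 to 13.1). Isg15, a ubiquitin-like protein, was 8.83-fold lower (5.11 to 16.5) and Gbp3 9.80-fold lower (5.88 to 17.5). Phf11d was 15.1-fold lower (4.90 to 75.4), the class I-like gene H2-T24 7.94-fold lower (4.26 to 16.4). The corrected median of the list was -1.37, with 24 members lower.

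Other genes among the 10 lowest were Gabrb2, a subunit of the GABA-A receptor, 7.04-fold lower (5.47 to 9.18), and Zbed6, 7.08-fold lower (4.28 to 12.5). Of 32 activity-induced immediate early genes, 14 were lower and 2 higher, with a median of -0.43 (corrected -0.62, 19 lower). Egr2 was 3.59-fold lower (2.13 to 6.37), Egr3 2.77-fold lower (2.53 to 3.04) and Homer1 2.71-fold lower (2.41 to 3.05). Among 28 microglial and macrophage markers, 12 were lower and 1 higher, with a median of -0.36 (corrected -0.49). P2ry12, a purine receptor of resting microglia, was 3.25-fold lower (2.53 to 4.22), Fcgr1 2.93-fold lower (2.0 to 4.40) and Fcrls 2.70-fold lower (2.15 to 3.40). Aif1, which encodes the microglial protein Iba1, had 73 counts in sham and 57 in vehicle, a ratio of 0.966 (0.671 to 1.38).

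Pituitary genes were higher in vehicle in 7 of 9 measured cases, with a median of 4.32, or 4.75 with genes at 0 in sham set to their lower bound. Besides Gh, prolactin (Prl) was at least 2312-fold higher with 5606 counts against 0, and the growth hormone-releasing hormone receptor Ghrhr at least 34.2-fold higher with 83 against 0. Pomc, the precursor of corticotropin, was 265-fold higher (204 to 351), and Cga, the shared subunit of glycoprotein hormones, 96.5-fold higher (26.3 to 804) with 156 counts against 2. Gh, Prl, Pomc and Cga together made up 0.362% of the vehicle counts. The epithelial adhesion gene Epcam was 37.7-fold higher (10 to 319) with 61 counts against 2, and Cyp2f2 9.18-fold higher (5.0 to 18.4).

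Markers of some deep brain regions and of blood were also higher in vehicle. Unequal dissection or blood content of the samples could move such markers, and this was not tested. Of 15 genes of brainstem and monoamine neurons, 9 were higher and 1 lower, with a median of 0.62 (corrected 0.35). The serotonin transporter Slc6a4 was 127-fold higher (22.4 to 5082) with 103 counts against 1, the neuronal glycine transporter Slc6a5 23.5-fold higher (7.65 to 117) with 57 against 3, and Tph2, which makes serotonin, 4.95-fold higher (2.83 to 9.17). Of 20 hypothalamic peptide neuron genes, 8 were higher and 0 lower, among them Pomc, which the pituitary list also holds, Gpx3 at 2.26-fold (2.01 to 2.55) and oxytocin (Oxt) at 2.27-fold (1.88 to 2.74). Their median was 0.50, and 0.11 after correction, at percentile 92.3. Red blood cell genes were higher in 5 of 7 cases, with a median of 1.41 (corrected 1.01). Alas2, the first enzyme of haem synthesis in red cells, was 3.68-fold higher (2.58 to 5.36) and Hbb-bs 3.39-fold higher (3.05 to 3.78). Hba-a2 was 4.71-fold higher (3.15 to 7.24) and, like Hbb-bs, has a near-identical copy.

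For neurogenesis, the list of 30 neural progenitor and newborn neuron genes had 2 members higher, 5 lower and 23 that did not pass the size rule, with a median of -0.05 at percentile 43.7; after correction 0 were higher and 6 lower, with a median of -0.10 at percentile 15.7. The proneural factor Neurod1 was 2.10-fold lower (1.54 to 2.88) and the stem cell factor Sox2 1.67-fold lower (1.46 to 1.91). Nes, which encodes nestin, had a ratio of 1.35 (1.08 to 1.70). The corrected log2 ratio of Dcx was -0.28, inside the 1.5-fold limit, while that of Sox2 was -0.97. Of 22 cell division genes, 3 were lower and 0 higher, with a median of -0.27. Bub1b was 3.00-fold lower (1.73 to 5.46), Mcm3 2.90-fold lower (1.67 to 5.30) and Rrm2 1.94-fold lower (1.04 to 3.81). Mki67, a marker of dividing cells, had 33 counts in sham and 15 in vehicle, a ratio of 0.562 (0.284 to 1.06), so that a difference was not detectable at this depth.

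For angiogenesis, the 31 angiogenic factors and receptors included 3 higher and 6 lower genes, with a median of -0.07 at percentile 34.9 (corrected 2 higher and 3 lower). Angptl4 was 3.53-fold higher (2.61 to 4.81), and the receptors Nrp1 and Kdr were 2.19-fold lower (1.68 to 2.89) and 1.77-fold lower (1.38 to 2.29). Vegfa, the main endothelial growth factor, had a ratio of 0.677 (0.609 to 0.753), short of the size rule. The 27 endothelial markers had 5 higher and 3 lower members and a median of 0.04 (corrected 3 higher and 4 lower). The tight junction gene Ocln was 2.80-fold lower (1.95 to 4.11), the phosphatase Ptprb 2.25-fold lower (1.92 to 2.64) and von Willebrand factor (Vwf) 2.17-fold higher (1.93 to 2.45). Pecam1 and Cldn5 had ratios of 1.21 (1.06 to 1.38) and 1.12 (0.993 to 1.26). Of 17 mural cell genes, 3 were higher and 1 lower, with a median of 0.06 (corrected 1 each); Acta2 was 1.68-fold higher (1.47 to 1.92).

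Neurotrophic genes had 1 higher and 3 lower members of 19 and a median of -0.18 (corrected 0 higher and 1 lower, median -0.07). Bdnf, brain-derived neurotrophic factor, was 2.29-fold lower (1.83 to 2.89), and Nrtn was 2.01-fold higher (1.53 to 2.64). Of 29 Wnt pathway genes, 1 was higher and 3 lower, with a median of -0.16 at percentile 14.97 (corrected -0.21, percentile 0.70). The kinase Gsk3b was 1.72-fold lower (1.61 to 1.84), Fzd6 1.71-fold lower (1.30 to 2.28) and Ctnnb1 1.56-fold lower (1.48 to 1.64).

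Glial genes did not move together. Gfap, the intermediate filament of reactive astrocytes, was 1.81-fold lower in vehicle (1.74 to 1.88), at 238 against 430 CPM. Of 23 reactive astrocyte genes, 2 were higher and 5 lower, with a median of 0.14 at percentile 88.4; after correction 4 were higher and 3 lower, with a median of -0.08 at percentile 27.4. Besides Lcn2, the glucocorticoid-induced Fkbp5 was 2.65-fold higher (2.46 to 2.86), and Tgm1 was 8.69-fold lower (3.16 to 33.3) with 4 counts in vehicle. Among 22 homeostatic astrocyte genes, 2 were higher and 2 lower, with a median of 0.16 (corrected 1 and 2, median 0.02). The water channel Aqp4 was 2.88-fold lower (2.52 to 3.30), and Aldh1l1 was 1.65-fold higher (1.53 to 1.77). Of 25 myelin genes, 3 were higher and 6 lower, with a median of -0.14 at percentile 2.35 (corrected 2 and 3, median -0.19). Ugt8a, an enzyme of myelin lipid synthesis, was 2.69-fold lower (2.24 to 3.26), and the lipocalin Apod was 2.63-fold higher (2.54 to 2.74). Of 20 oligodendrocyte precursor genes, 3 were lower and 0 higher, with a median of -0.11.

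Inflammatory genes were sparse in these counts. Of 36 listed cytokine, chemokine and adhesion genes, 17 were among the counted genes and 13 were measured. Il1b, Il6, Tnf and Ccl2 were among those not counted. Of the 13 measured genes, 4 were higher and 1 lower, with a median of 0.39 at percentile 99.2. Icam1, an endothelial adhesion molecule, was 3.91-fold higher (2.69 to 5.79), the NF-kappaB inhibitor Nfkbia 1.96-fold higher (1.73 to 2.21) and Socs3 1.94-fold higher (1.43 to 2.65). Of 34 listed leukocyte genes, 14 were among the counted genes and 9 were measured. These were higher in 2 and lower in 1 of 9 cases, with a median of 0.44 (corrected 0.07). The neutrophil protein gene S100a9 was 19.4-fold higher (6.24 to 97.4) with 47 counts against 3, and Ptprc, the common leukocyte antigen, was 3.84-fold lower (1.76 to 9.53). Phagocytic microglia genes were higher in 5 and lower in 0 of 19 cases, with a median of 0.23, and Apoe was 1.65-fold higher (1.63 to 1.67). After correction 2 were higher and 2 lower, with a median of 0.06 at percentile 74.2, and the log2 ratio of Apoe was 0.218, inside the 1.5-fold limit. Complement and antigen presentation genes had 1 higher member (C2) and 0 lower of 25, with a median of 0.09; after correction 1 was higher and 4 lower, with a median of -0.18 at percentile 5.42.

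Neuronal genes were lower as lists. The medians were -0.24 for 24 forebrain glutamatergic genes, -0.23 for 28 synapse genes and -0.29 for 21 GABAergic genes, at percentiles 0.04, 0.00 and 1.07, with 7, 6 and 6 members lower and 0, 0 and 1 higher. The glutamate receptor genes Gria2 and Gria3 were 2.21-fold lower (2.09 to 2.33) and 2.04-fold lower (1.89 to 2.19), and the cannabinoid receptor Cnr1 2.19-fold lower (1.98 to 2.42). After correction, 1 glutamatergic, 1 synapse and 4 GABAergic members were lower and 0, 1 and 0 higher, and the medians were -0.18, -0.09 and -0.16. Regional lists gave 1 higher and 6 lower of 26 for cortical layers, 1 and 3 of 22 for striatum, 3 and 4 of 21 for hippocampus, 1 and 3 of 22 for thalamus, and 2 and 2 of 17 for cerebellum; after correction these were 0 and 2, 0 and 3, 1 and 2, 0 and 0, and 1 and 1. Among these, the hippocampal C1ql3 was 4.07-fold lower (3.00 to 5.63) and the striatal Pde10a 2.10-fold lower (1.93 to 2.28).

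Stress and metabolic lists were mixed. Of 40 nuclear genes of oxidative phosphorylation, 20 were higher and 0 lower, with a median of 0.58; after correction the median was 0.29 and 4 were higher. Uqcr11 was 1.72-fold higher (1.60 to 1.85). Among 29 antioxidant genes, 8 were higher and 1 lower, with a median of 0.48 (corrected 0.18, 4 higher), and the metallothionein Mt1 was 2.19-fold higher (2.10 to 2.28). Of 25 apoptosis and p53 target genes, 4 were higher and 1 lower (corrected 2 and 0); the cell cycle inhibitor Cdkn1a was 4.90-fold higher (4.38 to 5.49). Of 30 glycolysis and hypoxia genes, 5 were higher and 1 lower (corrected 1 and 1), with Ddit4 2.19-fold higher (2.04 to 2.35). Heat shock and endoplasmic reticulum stress genes had 2 higher and 2 lower of 31 (corrected 1 and 1), and matrix remodelling genes 4 higher and 3 lower of 36 (corrected 1 and 4). Choroid plexus genes were higher in 6 and lower in 1 of 21 cases (median 0.31), ependymal genes in 6 and 2 of 21 (median 0.27), and meningeal fibroblast genes in 3 and 5 of 29 (median -0.27). After correction these were 8 and 1 (median 0.35), 3 and 1 (median 0.19), and 2 and 3, with the meningeal median near 0 at percentile 55.2. Of 13 mitochondrially encoded protein genes, 0 were higher and 1 lower, and of 7 skeletal muscle genes 3 were higher and 0 lower (corrected 1 and 0). The Y-linked genes Uty, Ddx3y and Eif2s3y were lower in vehicle, Kdm5d had a ratio of 0.703, and the median of the 4 was -0.87 (corrected -0.38); after correction only Uty passed.

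**Figure D2:**
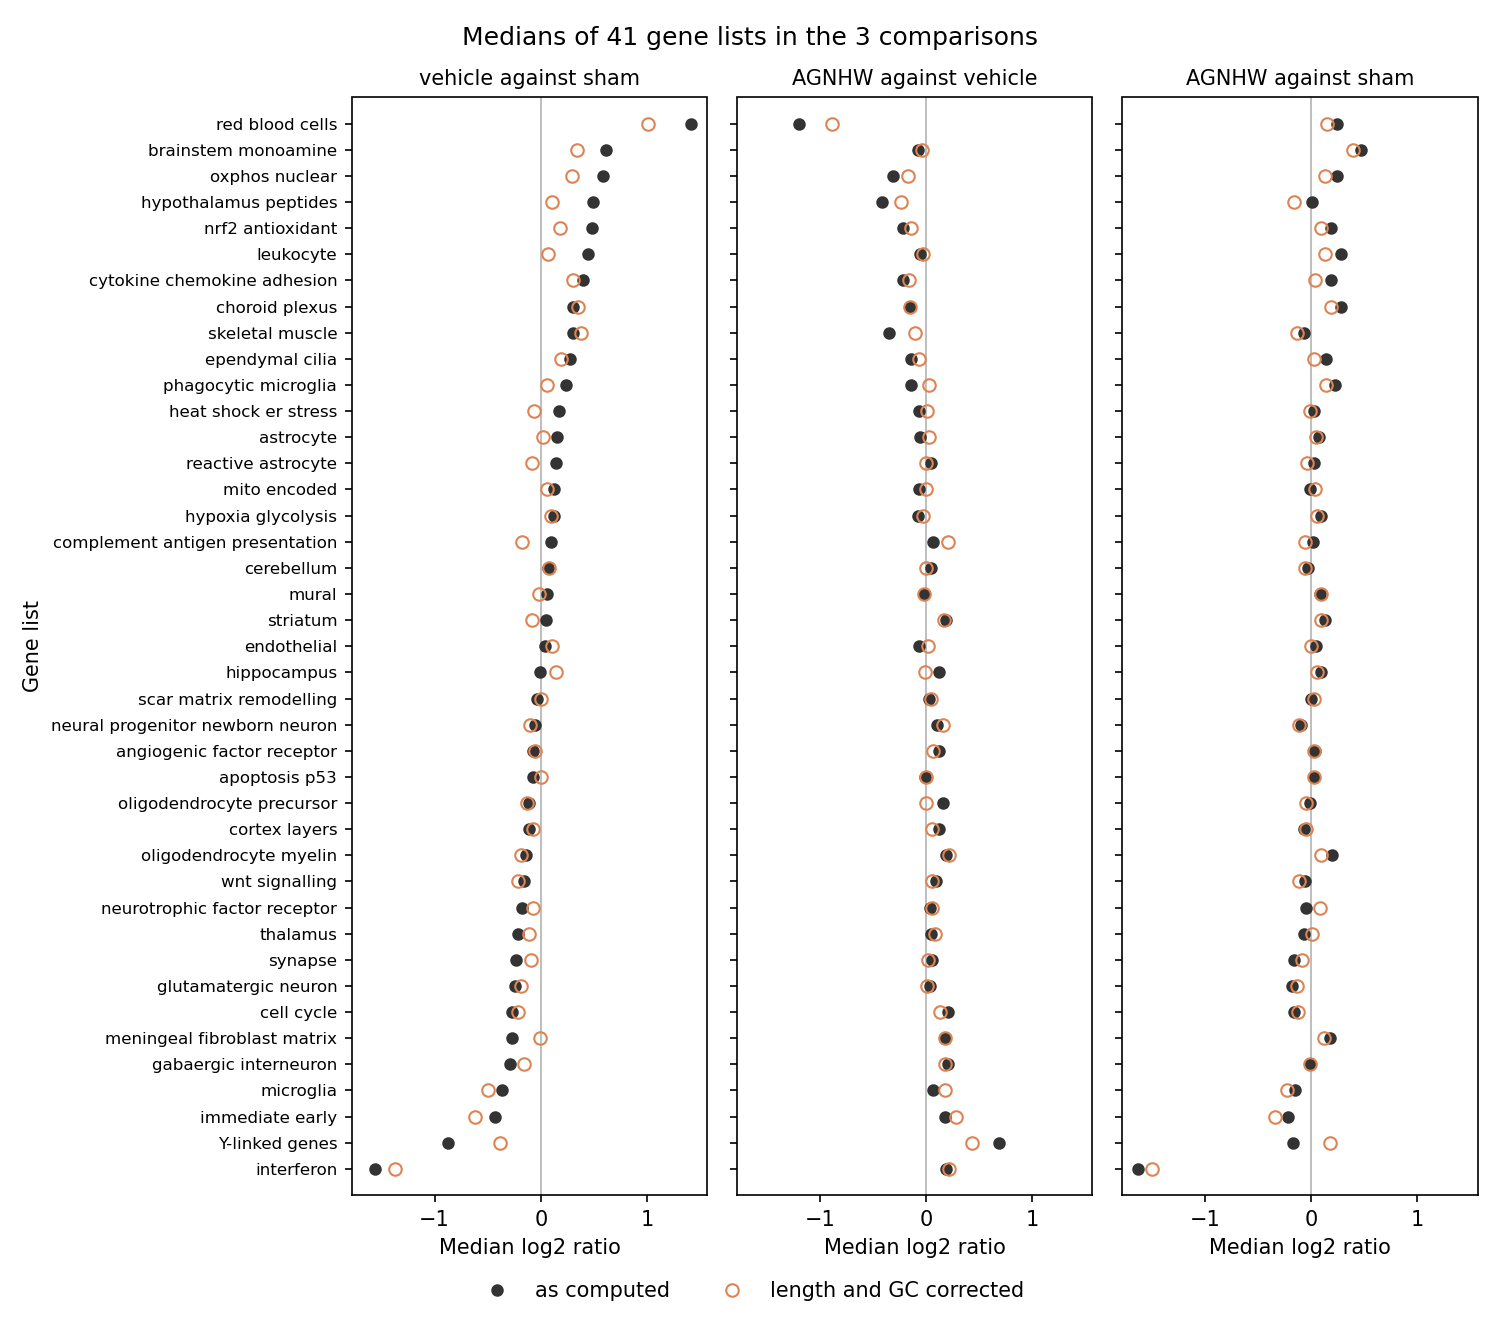
Median log2 ratio of 41 gene lists (rows) in the 3 comparisons (panels), as computed (filled) and after correction for transcript length and GC content (open); the pituitary list, with medians of 4.32, -4.07 and 0.08, is left off the scale. The interferon list lay at -1.56, 0.19 and -1.63, apart from the other lists shown in both comparisons with sham.

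The comparison of AGNHW with vehicle asks what the treatment added to the model. This takes the AGNHW mice as occluded, which the labels do not state. The AGNHW library had far fewer pituitary and red blood cell transcripts than the vehicle library, and more of several immediate early and microglial genes, while the neurogenic and angiogenic lists had members past the size rule both ways. Egr3 and Egr1, transcription factors induced by neuronal activity, were 1.75-fold (1.58 to 1.93) and 1.73-fold (1.62 to 1.83) higher with AGNHW. Dcx had a ratio of 1.22 (1.01 to 1.47) and Vegfa 1.29 (1.15 to 1.44), both short of the size rule. Nes was 1.64-fold lower with AGNHW (1.29 to 2.09).

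Fewer genes passed than between vehicle and sham, 624 higher and 398 lower, so 61.1% of them were higher; with plain CPM the numbers were 808 and 309, or 72.3% higher. After correction for length and GC content, 458 were higher and 265 lower, of which 368 and 216 had also passed in the same direction without it. Length and GC content explained 27.0% of the variance of the log2 ratio. Of the 42 lists, 8 had medians above and 6 below the central 95% of random lists.

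Of the 30 neural progenitor and newborn neuron genes, 1 was higher, 1 (Nes) lower and 28 did not pass; the median was 0.11 at percentile 89.5, and 0.16 at percentile 99.6 after correction. The homeobox gene Dlx6 was 1.54-fold higher (1.22 to 1.95), while Sox2 had a ratio of 1.42 (1.24 to 1.63), short of the size rule. Of 22 cell division genes, 3 were higher and 1 lower, with a median of 0.21 at percentile 96.0 (corrected 0.13, percentile 84.2). Bub1b was 2.69-fold higher (1.54 to 4.95), Ccna2 2.01-fold higher (1.12 to 3.77) and Aurka 1.72-fold higher (1.11 to 2.71). Mki67 had 15 counts in vehicle and 20 in AGNHW, a ratio of 1.11 (0.540 to 2.33).

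Of the 31 angiogenic factors and receptors, 5 were higher, 4 lower and 22 did not pass, with a median of 0.12 at percentile 92.7 (corrected 0.07, percentile 86.5). Fibroblast growth factor 2 (Fgf2) was 2.07-fold higher (1.35 to 3.25), Angptl4 2.23-fold lower (1.72 to 2.91) and Tgfb1 1.92-fold lower (1.53 to 2.42). Kdr had a ratio of 1.26 (0.963 to 1.65). Endothelial markers had 1 higher and 1 lower member of 27 and a median of -0.06 at percentile 11.4 (corrected 0.02, percentile 67.1). Ocln was 2.48-fold higher (1.71 to 3.66) and Ramp2 1.84-fold lower (1.60 to 2.12), whereas Pecam1 and Cldn5 had ratios of 0.915 (0.801 to 1.05) and 1.21 (1.08 to 1.35). None of 17 mural cell genes passed. Neurotrophic genes were higher in 2 of 19 cases, Fgf2 and neurotrophin 3 (Ntf3) at 1.87-fold (1.15 to 3.12), and Bdnf had a ratio of 1.14 (0.882 to 1.48). Among 29 Wnt genes, the transcription factor Lef1 was higher at 1.54-fold (1.12 to 2.12) and 0 were lower.

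Of 32 immediate early genes, 4 were higher and 1 lower with AGNHW, with a median of 0.18 at percentile 99.8 (corrected 0.29). Egr2 was 1.90-fold higher (1.07 to 3.51). Microglial markers were higher in 4 and lower in 0 of 28 cases, with a median of 0.07 at percentile 71.7 (corrected 0.18, percentile 99.9). Adgre1, a macrophage surface receptor, was 2.55-fold higher (1.45 to 4.70), the microglial transcription factor Sall1 2.02-fold higher (1.65 to 2.48) and P2ry12 1.55-fold higher (1.17 to 2.07). Myelin genes were higher in 3 and lower in 0 of 25 cases, with a median of 0.19 at percentile 99.99; Ermn was 1.69-fold higher (1.46 to 1.97), Opalin 1.51-fold higher (1.30 to 1.75) and Il33 1.88-fold higher (1.60 to 2.23). After correction the myelin median was 0.21 with 1 member higher, and the log2 ratio of Ermn was 0.548, inside the 1.5-fold limit. GABAergic genes were higher in 2 of 21 cases (median 0.21, percentile 99.8), including the noncoding Dlx6os1 at 2.13-fold (1.51 to 3.05), and striatal genes in 2 of 22 (median 0.19, percentile 99.9), including Pde10a at 1.77-fold (1.62 to 1.92). No glutamatergic or synapse gene passed, with medians of 0.03 and 0.06 at percentiles 94.9 and 99.8 (corrected 0.01 and 0.01, percentiles 83.2 and 91.4).

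Interferon-stimulated genes were higher in 4 and lower in 0 of 27 cases, with a median of 0.19 at percentile 96.2. After correction 2 were higher, with a median of 0.22 at percentile 98.85, outside the central 95%. Ifit1 was 2.25-fold higher (1.05 to 5.21), Mx2 1.99-fold higher (1.01 to 4.13) and Oasl2 1.83-fold higher (1.18 to 2.89), at 3.72 CPM against 23.5 CPM in sham. Among the 10 highest genes were Gbp5 at 3.86-fold (1.99 to 8.22) and the cytosolic DNA sensor Aim2 at 3.12-fold (1.89 to 5.40). Inflammatory genes were lower in 3 and higher in 0 of 13 cases, with a median of -0.21 at percentile 1.81 (corrected -0.16, percentile 3.11, inside the central 95%). Icam1 was 2.72-fold lower (1.95 to 3.83) and Nfkbia 1.71-fold lower (1.52 to 1.93), with ratios of AGNHW over sham of 1.44 (0.930 to 2.24) and 1.14 (1.0 to 1.30). Lcn2 and Gfap hardly differed between AGNHW and vehicle, with ratios of 0.957 (0.815 to 1.12) and 1.04 (0.997 to 1.09).

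Pituitary genes were lower with AGNHW in 6 of 9 cases. Gh had 4 counts and Prl 1, and the ratios of vehicle over AGNHW were 11727 (4580 to 43041) and 6731 (1208 to 265919). Pomc was 360-fold lower (265 to 505) and Cga, at 0 counts, at least 62.4-fold lower. Epcam was 73.2-fold lower (12.7 to 2940) with 1 count. Hypothalamic peptide genes were lower in 6 of 20 cases (median -0.41, corrected -0.23), including Cartpt at 1.98-fold (1.70 to 2.31). Of 15 brainstem and monoamine genes, 3 were lower and 1 higher, Slc6a5 17.1-fold lower (6.33 to 64.9), Slc6a4 6.18-fold lower (3.8 to 10.5) and Tph2 3.66-fold lower (2.2 to 6.31). Red blood cell genes were lower in 5 of 7 cases (median -1.20, corrected -0.88), with Alas2 5.0-fold lower (3.34 to 7.72). Antioxidant genes were lower in 2 of 29 cases, Gpx3 and Mt1, with a median of -0.22; after correction the median was -0.14 and neither passed. None of the 40 oxidative phosphorylation genes passed, with a median of -0.31 at percentile 0.00 (corrected -0.17).

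The remaining lists had few members past the size rule. Meningeal fibroblast genes were higher in 5 of 29 cases (median 0.18, percentile 98.7), among them the transcription factors Foxc2 and Foxc1 at 2.40-fold (1.52 to 3.91) and 1.60-fold (1.18 to 2.19). Ependymal genes were lower in 3 of 21 cases (0 after correction), choroid plexus genes in 1 of 21 (Folr1) and skeletal muscle genes in 1 of 7 (Actn3). Reactive astrocyte genes had 1 higher and 1 lower of 23, astrocyte genes 1 higher (Aqp4, 1.77-fold, 1.53 to 2.05, which did not pass after correction) and 0 lower of 22, and precursor cell genes of oligodendrocytes 1 higher of 20. Cortical layer genes had 1 higher and 1 lower of 26, hippocampal and thalamic genes 2 higher each, and cerebellar genes 1 higher and 1 lower of 17. Phagocytic microglia, leukocyte, apoptosis and matrix remodelling lists had 1 higher member each, and the heat shock, hypoxia and complement lists had none. The corrected median of the complement list was 0.20 at percentile 99.6, with no member past the size rule. Of the Y-linked genes, Eif2s3y and Uty were 1.89-fold (1.62 to 2.21) and 1.99-fold (1.29 to 3.13) higher. Of 13 mitochondrially encoded genes, mt-Nd3 and mt-Atp8 were higher at 3.78-fold (3.19 to 4.51) and 1.53-fold (1.46 to 1.61), and mt-Atp6 was 1.77-fold lower (1.71 to 1.83).

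Several of the 10 highest genes in AGNHW over vehicle have near-identical copies and are uncertain. The chemokine gene Ccl21b had 148 counts in AGNHW and 0 in the other libraries, at least 41.1-fold above vehicle. Srp54b was 13.9-fold higher (7.96 to 26.5), Eif3j2 4.09-fold higher (2.18 to 8.37) and Tmem254a 2.67-fold higher (2.32 to 3.08). Besides Gbp5, Aim2 and mt-Nd3, given above, the others were Adamts3 at 4.04-fold (2.48 to 6.90), Tm6sf2 at 3.10-fold (1.82 to 5.54) and Zfp882 at 3.02-fold (1.71 to 5.63). Among the 10 lowest, outside the pituitary and brainstem lists, Cyp2f2 was 5.94-fold lower (3.55 to 10.5) and Gnb3 6.00-fold lower (3.35 to 11.5).

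The comparison of AGNHW with sham shows how far the treated library lay from the operated control. Lcn2, Cdkn1a, the lipid droplet gene Plin4 and Fkbp5 were higher in AGNHW than in sham, and interferon-stimulated genes lower, as they were in vehicle. Lcn2 was 38.0-fold higher (19.8 to 83.9), Cdkn1a 4.21-fold (3.77 to 4.72), Plin4 3.98-fold (3.53 to 4.49) and Fkbp5 2.57-fold (2.39 to 2.76). Irf7 was 8.18-fold lower (5.88 to 11.7). Dcx was 1.70-fold lower (1.47 to 1.98), and Gfap 1.74-fold lower (1.67 to 1.80); the corrected log2 ratio of Dcx was -0.289, inside the 1.5-fold limit, and that of Gfap -0.937.

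Between these libraries, 517 genes were higher and 851 lower, and 412 and 487 after correction for length and GC content, which explained 38.6% of the variance. Of the 42 lists, 7 lay above and 4 below the central 95% of random lists. Interferon-stimulated genes were lower in 20 and higher in 0 of 27 cases, with a median of -1.63 (corrected -1.49). Ifi44 was 31.1-fold lower (8.25 to 262), Gbp3 8.19-fold (5.30 to 13.2), Oasl2 6.31-fold (4.88 to 8.27), Usp18 7.93-fold (4.34 to 15.9) and Rsad2 7.63-fold (3.46 to 19.8). Immediate early genes were lower in 8 and higher in 1 of 32 cases, with a median of -0.22 (corrected -0.34). Microglial genes were lower in 7 of 28 cases (median -0.15, corrected -0.23), with Fcgr1 2.80-fold lower (1.97 to 4.04) and P2ry12 2.10-fold lower (1.72 to 2.58). The glutamatergic and synapse lists stayed low, with medians of -0.18 and -0.16 at percentiles 0.03 and 0.00 and 5 and 2 members lower; after correction no member passed and the medians were -0.14 and -0.09. Reactive astrocyte genes were higher in 5 and lower in 4 of 23 cases (corrected 7 and 4). Meningeal fibroblast, phagocytic microglia, antioxidant and oxidative phosphorylation lists lay above the central 95%, with medians of 0.18, 0.22, 0.19 and 0.25 (corrected 0.12, 0.14, 0.10 and 0.13); after correction the antioxidant list lay inside it, at percentile 96.95.

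Neural progenitor and newborn neuron genes had 1 higher and 3 lower of 30, with a median of -0.10 at percentile 16.3 (corrected 1 and 1, median -0.12). Hes5, a Notch target, was 1.98-fold higher (1.46 to 2.71), and the radial glial gene Fabp7 was 1.81-fold lower (1.46 to 2.24). Angiogenic genes had 3 higher and 2 lower of 31 (median 0.04), with adrenomedullin (Adm) 1.98-fold higher (1.34 to 2.98) and the receptor Met 2.43-fold lower (1.63 to 3.68). Endothelial genes had 2 higher and 1 lower of 27 (median 0.04), with Vwf 2.46-fold higher (2.19 to 2.75). Kdr, Vegfa, Pecam1 and Cldn5 had ratios of 0.710 (0.570 to 0.884), 0.871 (0.794 to 0.956), 1.11 (0.969 to 1.26) and 1.35 (1.21 to 1.51). Bdnf was 2.01-fold lower (1.64 to 2.47).

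Brainstem and monoamine genes were higher in AGNHW than in sham in 7 and lower in 1 of 15 cases, with a median of 0.47 (corrected 0.39), including Slc6a4 at 20.6-fold (3.30 to 854) with 20 counts against 1 and Ddc at 2.12-fold (1.85 to 2.44). No pituitary or red blood cell gene passed. Choroid plexus genes were higher in 3 and lower in 1 of 21 cases (median 0.29, corrected 0.19), and myelin genes had a median of 0.20 (corrected 0.09, percentile 95.35) with 1 higher and 1 lower of 25. S100a9 was 16.8-fold higher (5.43 to 84.4) with 49 counts against 3, Lrg1 3.73-fold higher (2.80 to 5.04), Depp1 5.50-fold higher (3.14 to 10.3) and Adamts14 3.79-fold higher (2.42 to 6.16). The copy genes Plac9a, at 6.49-fold (4.50 to 9.61), and Tmem181b-ps, 4.28-fold lower (3.94 to 4.65), are uncertain.

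Setting the comparisons beside each other, 321 genes were higher and 661 lower than sham in both other libraries. In the opposite sense, 230 genes were higher in vehicle than sham and lower in AGNHW than vehicle, and 457 were lower and then higher (corrected 129 and 290). These pairs share the sham or the vehicle library, so unchanged libraries give such genes as well. In simulations of 3 unchanged libraries, added after the data were seen, the mean numbers were 10.9, 6.82, 9.87 and 14.4 in that order with counting error only, and 461, 361, 371 and 468 with an assumed variation of 0.2 between samples. With that assumed variation, 2530 unchanged genes passed between AGNHW and vehicle and 2633 between AGNHW and sham. The real libraries gave fewer, 624 higher and 398 lower, and 517 and 851, so 0.2 was too large there. Between vehicle and sham they gave more, 1348 and 2207 against 2567. The 661 genes lower in both lay above the highest draw, 410, while the 321 and 230 lay below the lowest, 423 and 324. The 457 lay within 385 to 509. Since the true variation was not measured, the overlaps do not show a shared or reversed response. Of the 3555 genes past the size rule between vehicle and sham, 93.9% had a log2 ratio of AGNHW over vehicle of the opposite sign. In simulations of the same kind this share was 94.3% with counting error only and 85.1% with an assumed variation of 0.2 between samples. The covariance of the log2 ratios was -0.150, against -0.0170 and -0.0968 in those simulations, and -0.102 after correction for length and GC content. With the vehicle reads split at random into 2 parts, each used in 1 comparison, it was -0.129, which removes the counting error that the comparisons share but not the variation of the sample itself.

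**Figure D3:**
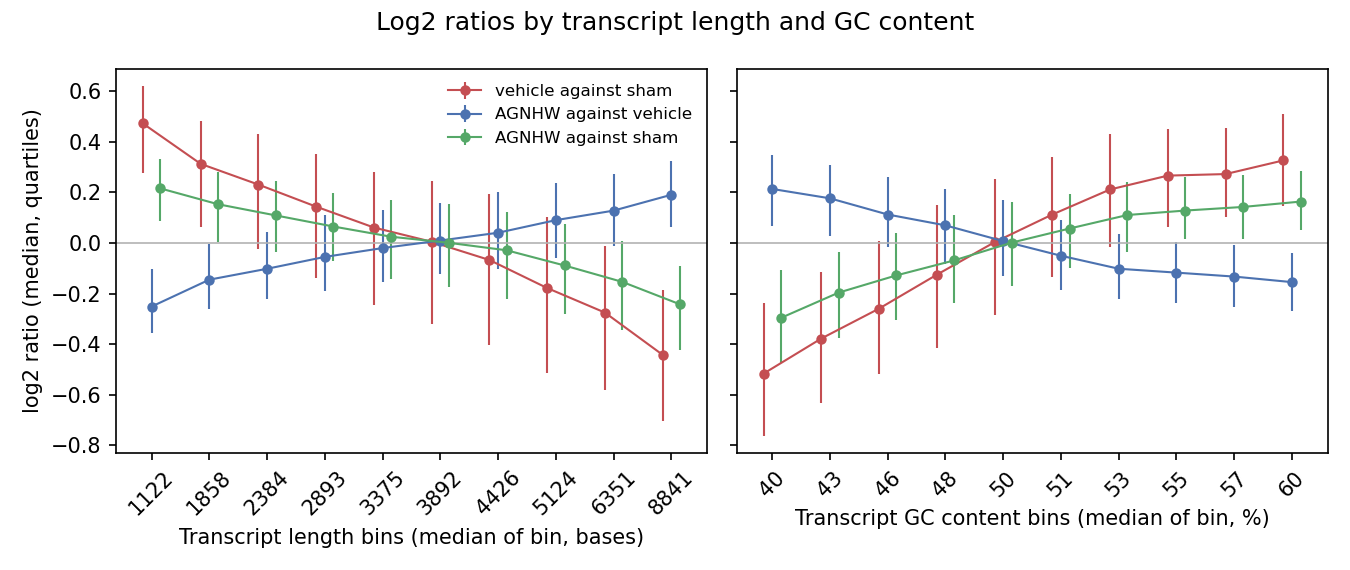
Log2 ratios in 10 equal bins of transcript length (left) and GC content (right) over 9941 genes of at least 10 CPM, with medians as points and quartiles as bars, for the 3 comparisons. Vehicle against sham ran from 0.47 in the shortest to -0.44 in the longest bin, and from -0.52 in the lowest to 0.33 in the highest bin of GC content.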

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

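The correction for transcript length and GC content was chosen after seeing the data; the other alternatives were planned. The numbers of lists beyond the percentiles stayed within 1.5 times under every alternative run, and no list beyond them changed sign. Other list medians near 0 did, 24 of 126 with the correction, 11 with plain CPM, 8 without shared members and 5 with upper-quartile factors, and 8 of 114 at a mean CPM of at least 10. Which lists lay beyond the percentiles changed with the correction. For AGNHW against vehicle, the synapse, cortical layer and inflammatory lists came inside. The neural progenitor, microglial, interferon, complement and choroid plexus lists went outside. For vehicle against sham, the leukocyte, hypothalamic and Y-linked lists came inside, and the Wnt and skeletal muscle lists went outside. For AGNHW against sham, the antioxidant and myelin lists came inside and the microglial list went outside. Of 189 genes picked for single values that passed the size rule between vehicle and sham, the correction took 67 inside 1.5-fold, against 15 of 91 for AGNHW against vehicle and 32 of 113 for AGNHW against sham; none changed sign. For vehicle against sham, plain CPM gave 890 higher genes, a mean CPM of at least 10 gave 710 higher and 1235 lower, a ratio of at least 2 gave 307 and 711, a ratio of at least 3 gave 81 and 133, and the correction 737 and 1041. For AGNHW against vehicle, the higher CPM minimum gave 137 and 73, the ratio of 2 gave 175 and 116, the ratio of 3 gave 31 and 27, and the correction 265 lower. For AGNHW against sham these gave 119 and 313, 179 and 192, 43 and 43, and 487 lower. The stricter limits leave fewer genes by construction. Plain CPM drops the TMM factors, which shifts all ratios of a comparison by the same factor. For the correction the cause was not tested. The share of genes that moved back toward sham was 88.7% with the vehicle reads split, 97.7% at the higher CPM minimum and 90.9% after the correction. The covariance was -0.129, -0.125 and -0.102 in that order. The split removes the counting error that the comparisons share, and for the others the cause was not tested. Of 126 list medians, 52 moved with the correction, 25 with plain CPM, 8 without shared members, 2 with the prior count of 0.5 and 1 with upper-quartile factors; 18 of 114 moved at the higher CPM minimum. DESeq2 size factors moved none of these. No paired analysis was possible because each group had 1 library, and leaving out a library was not possible for the same reason. Depth limits the low genes, since 3 counts are 0.159 to 0.197 CPM.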

Other observations

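Of the tests below, those of vehicle RNA mixed into the AGNHW sample and of microglia in the sham sample were chosen after the result was seen, as was the correction for length and GC content.

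Genes of ribosomal proteins, which were not among the lists, moved with the vehicle library. Of 74 such genes, 43 were higher in vehicle than in sham and 0 lower, with a median log2 ratio of 0.62 (corrected 0.32), and their share of all counts was 1.09% in sham, 1.59% in vehicle and 1.36% in AGNHW. Their median transcript length was 1077 bases, against 3302 for all genes. Between AGNHW and vehicle the median was -0.28 (corrected -0.13) with none past the size rule. Mitochondrially encoded genes took 5.78%, 5.25% and 5.32% of the counts in the same order of libraries.

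Genes higher than sham in both other libraries included several that glucocorticoids induce. Fkbp5, Plin4, Cdkn1a and Lcn2 are given above, and Map3k6, Sult1a1, Arrdc2 and Hif3a, named here after their values were seen or as members of the test list, were 3.53-fold, 3.39-fold, 3.08-fold and 2.36-fold higher in vehicle than in sham and 2.89-fold, 2.66-fold, 1.98-fold and 2.27-fold higher in AGNHW. The hypothesis that glucocorticoid-responsive genes as a set were higher in both was tested on 10 induced genes written down before their values were seen. Their median corrected log2 ratio against sham was 0.333 in vehicle and 0.294 in AGNHW, below the 0.5 set in advance as support and above the 0.2 set against it, so the test leaves the hypothesis open. Of the 10, 5 were higher in vehicle and 3 in AGNHW, while Klf9 had a ratio of 0.634 in vehicle, and Sgk1 and Tsc22d3 had ratios of 1.21 and 1.24.

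Pituitary hormone genes reached 0.362% of the vehicle counts and were near 0 in the other libraries. If pituitary tissue had been in the vehicle sample, other genes of pituitary development should be higher as well. A second list of 15 such genes had 10 among the counted genes, of which 2 (Pitx1 and Tbx19) are also in the first list, and its median log2 ratio of vehicle over sham was 1.139, with 8 members higher and 2 (Ghsr and Eya1) lower. Counts were low, for example 33 against 1 for Lhx3 and 39 against 2 for Pitx1, so the median depends on the prior count, and some of the genes were already counted in sham, for example Eya1 at 6.80 CPM and Pax7 at 1.17 CPM. Pituitary tissue attached to the brain is therefore a candidate source, and a change within brain cells was not tested.

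Interferon-stimulated genes were higher in sham than in both other libraries. The trend with length and GC content could not account for this, because the corrected median of vehicle over sham was -1.374 against -1.56 without correction. More microglia in the sham sample would need microglial markers to be as low in vehicle as the interferon genes, but their median lay 1.195 above that of the interferon list. A state of the sham animals that differed by chance and an effect of occlusion may each remain, and they cannot be separated with 1 library per group.

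The AGNHW library moved back toward sham for 93.9% of the genes past the size rule, against 94.3% and 85.1% in simulations of unchanged libraries with counting error only and with an assumed variation of 0.2. The covariance of -0.150 was larger in size than the -0.0170 and -0.0968 of those simulations, but the variation was not measured here. In both comparisons with AGNHW, the assumed 0.2 passed more genes than the real libraries did, and between vehicle and sham fewer. Vehicle RNA mixed into the AGNHW sample is argued against by the pituitary genes, since the AGNHW counts of Gh and Prl were at most 0.01784% of those in vehicle. A trend in transcript length and GC content between the libraries explained 47.0% of the variance of vehicle over sham, short of the 50% set in advance for it as the cause and above the 10% set against it. That test held no AGNHW values, but the bins of transcript length do. For AGNHW over sham, the medians ran from 0.22 in the shortest bin to -0.24 in the longest. For AGNHW over vehicle they ran from -0.25 to 0.19, and for vehicle over sham from 0.47 to -0.44. The lowest and highest bins of GC content also placed AGNHW between the others, so it lay between them along this trend. After correction for the trend, the share was 90.9% and the covariance -0.102. The trend may account for part of the pattern. The rest cannot be told apart from differences between animals or from the treatment with 1 library per group.

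Other values stood out without a test. Gabra2 was at 72.8 CPM in sham, 48.3 in vehicle and 18.9 in AGNHW, and Wdfy1 at 37.8, 26.0 and 13.6, both named after their values were seen. Their corrected log2 ratios of vehicle over sham were 0.08 (Gabra2) and -0.168 (Wdfy1). Those of AGNHW over vehicle were -1.632 and -1.092, so after correction the low values were mainly those of the AGNHW library. Mice of different C57BL/6 substrains as a source of these differences were not tested, because the gene written down for that test was not analysed here, so this stays open. Among copy genes, Srp54b was at 1.97, 0.855 and 11.9 CPM in that order of libraries, against 16.3, 12.2 and 15.3 for Srp54c, also named after its values were seen. Srp54a, named in the same way, was at 4.62, 2.96 and 5.97 CPM. Like Srp54b, it passed the size rule as higher in AGNHW than in vehicle, at 2.02-fold (1.41 to 2.92). The mitochondrial genes mt-Nd3 and mt-Atp6 went opposite ways between AGNHW and vehicle, at 40.3 against 10.7 CPM and 321 against 569 CPM.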
